A study of Homo sapiens with 3 samples.

How the data were processed

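8-Oxo-7,8-dihydro-2'-deoxyguanosine (8-oxodG), a common oxidised form of guanine in DNA, was mapped in MCF10A cells, an established, non-tumorigenic line of human breast epithelium, held in G0, the resting state outside the cell cycle. Per the labels' protocols, sonicated genomic DNA was immunoprecipitated with an antibody against 8-oxodG and sequenced (DNA immunoprecipitation sequencing, DIP-seq). The labels gave 3 samples in 1 group, from 2 experiments. They named no second condition, and no untreated input or control antibody was analysed here. The submitters' processing notes named BWA, SAMtools, bedtools and the genome build hg18, without versions, roles or order.

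The authors deposited 1 peak list for the 3 samples together. Its coordinates start at 1. Per the file headers, each row gave a peak's position, its width, its summit, the signal at the summit as a pileup of fragments, a fold enrichment, and a p-value and a q-value as −log10. These are the columns that MACS2 writes, but the caller, its control, its settings and the way the samples were pooled are not given in the sources used here. The list holds no value per sample, so no mean ± SD over samples, no comparison of replicates and no value with a replicate left out could be had. The number of reads per sample is not given in the sources used here. Fold enrichment, p and q are the authors' own values for each peak and were used only to describe, rank and filter peaks within the list.

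In the deposited table the decimal points of fold enrichment, p and q were lost, with points standing as separators between groups of digits. The digits were intact. The place of the decimal point was restored from the Poisson relation between the columns. The background at the summit equals (pileup + 1) / fold enrichment − 1, and the p-value is the chance of more fragments than the pileup at that background. For 23640 of 23641 peaks a placement of both points met this relation within 0.01 on the −log10 scale. In the remaining peak, the one of highest pileup (400), the best placement missed by 4.22 out of 1002. The point in q was set to the largest value below p, and the order of q then followed that of p in all 23641 peaks. Tested on 2000 simulated rows with the points of fold enrichment and p removed, the procedure returned 100% of these values. The rule for q was not tested on simulated rows. The background at the summit, in fragments, was kept as a derived quantity, with a lowest value of 0.460.

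The build was checked against tables of chromosome lengths. Peaks reached past a chromosome end in 49 cases for hg17, 157 for hg19 and 286 for hg38, and in 0 for hg18. Of 23641 summits, 4 lay in assembly gaps of hg18, where 1487 were expected by chance because gaps make up 6.29% of the length. Cytogenetic bands of hg18 were taken from the R package circlize 0.4.16, and sequenced contigs of hg18 from IRanges 2.36.0, under R 4.3.3. Densities are peaks, counted by their midpoint, per Mb of sequenced contig. Chromosomes with no row in the list were left out, which left 23 chromosomes, 826 bands with sequence and 784 bands in the Giemsa classes gneg to gpos100. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

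All tests were two-sided. Mean densities of band classes were compared by exchanging the classes within chromosomes in 100000 permutations, with 95% intervals of the ratio from 10000 resamplings of bands. Terminal bands were the outermost stained band with sequence on each arm. For each of 10 lists of bands fixed beforehand, the median density was ranked among 10000 random lists with the same numbers per stain class, including the pericentromeric and variable classes where a list has such a band, and p was adjusted over the 10 lists by the Benjamini-Hochberg method. Clustering was measured by the variance-to-mean ratio of peaks in windows of 1 Mb, of which at least 50% was sequence, and by the distance between neighbouring midpoints. Both were set against 1000 random placements within the contigs of each chromosome. The placements ignored mappability. Densities of the 22 autosomes were correlated with chromosome length and with genes per sequenced Mb by permutation. Gene numbers per chromosome came from the RefSeq gene table of GRCh38.p14, of which only names, chromosomes and gene types were used. Genes of all types were counted, and protein-coding genes alone in 1 alternative. Intervals on the density of single bands are exact Poisson intervals that cover counting error only. Intervals on chromosomes and arms come from resampled bands.

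The tests were run on simulated bands with 784 stained members. Each band was drawn independently, with no likeness between neighbouring bands and no difference between chromosomes. The shares called therefore need not hold for this list, where density changes gradually along chromosomes. Without an added difference, 4% of 300 simulations were called for the stain test, 5% for the terminal test and 6.67% for a list of 10 terminal bands. With a 1.5-fold difference these shares were 100%, 98.7% and 54.7%, so a list of that size has limited power for such a difference. Both shares for the list count p before adjustment over the 10 lists. Under the adjusted p used for the data they can only be the same or lower. Lists of fewer bands were not simulated. Clustering was called in 5% of 20 random placements.

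The text names the 10 bands of highest and the 10 of lowest density among stained bands with at least 1 Mb of sequence, the 10 windows with the most peaks, up to 4 bands per list (the 2 highest and 2 lowest), the 5 widest peaks, the 3 longest stretches of sequence without a peak, the 3 chromosomes at each end of the ranking and the 10 peaks of highest fold enrichment. The results on stain classes, terminal bands, band lists, clustering and chromosome density were recomputed with other choices fixed before the data were examined, each where it applied. These were peaks joined within 1 kb, peaks at or above the median width, peaks at or above the median fold enrichment, covered bases in place of counts, autosomes only and bands of at least 1 Mb. Others were other window sizes, each chromosome left out, all stained classes as the comparison and permutation within stain classes. The list mean, protein-coding genes alone and the omission of chromosome 19 were also among them. Clustering was not recomputed with single autosomes left out. Stretches without a peak, fold enrichment per band and single peaks were not recomputed. Alternatives chosen after seeing the data left out arms of raised background, those at least 1.45 times the median arm, compared arms with all other autosomal arms or only with those of no raised background outside chromosome 19, or divided pileup and background by the background ratio of each arm, or of each band, and applied the lowest fold enrichment and p of the list again. Density against GC content was not run because no genome sequence was used here. Density against gene density by band, and any assignment of peaks to genes, were not run because the gene table is on another build.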

Results

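The data were 8-oxodG DIP-seq peaks from G0-arrested MCF10A cells, with 3 samples from 2 experiments combined in 1 list. The study's stated purpose was a genome-wide map of 8-oxodG, so the questions here are where the peaks lay and which chromosome regions held more or fewer of them. The list held 23641 peaks on chromosomes 1 to 22 and X, a density of 8.35 peaks per sequenced Mb. They covered 12.75 Mb, or 0.450% of the 2832 Mb of sequence. No peak overlapped another, and joining peaks within 1 kb left 22922. Because the list combines the samples, no value below has a replicate error, and p-values measure the spread between regions of the genome within this list.

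Peaks were narrow and of low height. The median width was 452 bp, with quartiles of 362 and 583 bp. The pileup at the summit had a median of 25 fragments and ranged from 10 to 400. Fold enrichment as given by the authors had a median of 11.7 and a lowest value of 7.001, and the lowest −log10 q was 7.95. Across peaks, which are not independent replicates, fold enrichment rose with width (Spearman's rho = 0.559) and hardly with the background at the summit (rho = 0.0831), which stands in its denominator. The pileup itself rose with the background (rho = 0.566). The lowest fold in the list forces part of this rise, since a peak over more background needs a higher pileup to be listed.

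The strongest enrichment in the list lay in 14q32.32, near the end of the long arm of chromosome 14. Of the 10 peaks of highest fold enrichment, 5 fell there. The highest (chromosome 14, 102441077 to 102442604, hg18) had a pileup of 400 and a fold enrichment of 275. The next (102406071 to 102406759) had a pileup of 200 and a fold of 138. The others in this band started at 102439119, 102412222 and 102433128, with folds of 93.8, 79.5 and 68.9. They belonged to a cluster of 14 separate peaks with a median background of 0.469, near the lowest in the list, and whether the fragments came from the genomic DNA of the cells was not tested. The remaining 5 of the 10 lay in 11p12 (fold 69.9), 6q14.1 (68.1), 16p13.12 (67.2), 21q22.2 (65.2) and 2q13 (64.7). The background was 0.460 at the peak in 11p12, the lowest in the list, and 0.503 at that in 21q22.2. At the peaks in 6q14.1, 16p13.12 and 2q13 it was above the median of 1.01 over all peaks. Whether the fragments of these 5 peaks came from genomic DNA was not tested either. No peak was assigned to a gene, because no gene annotation of hg18 was used here.

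The 5 widest peaks lay beside centromeres. In 21p11.2, on the short arm of chromosome 21, neighbouring peaks spanned 55899 bp (9795548 to 9851446) and 30350 bp (9852078 to 9882427). The others were in 10q11.21 (22102 bp, from 42110383), 4p11 (18062 bp, from 49336986) and 10p11.1 (15533 bp, from 39179243). Their pileups of 73 to 204 came with a background of 4.06 to 18.9 fragments, against a median of 1.01 over all peaks. Peaks of at least 5 kb numbered 28, and 20 of these were in pericentromeric or variable heterochromatin bands, which held 1.76% of all peaks.

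Whether peaks gathered in parts of the genome was tested against random placement on the same chromosome. Chromosome 19 held 8 of the 10 windows of 1 Mb with the most peaks, all on its long arm. The window from 55 to 56 Mb in 19q13.33 had 57 peaks, and the windows at 47 Mb in 19q13.2 and at 54 Mb in 19q13.33 had 53 and 50. Windows starting at 59 and 60 Mb in 19q13.42 had 49 and 47 peaks, those at 53 Mb in 19q13.32 and at 56 Mb in 19q13.33 had 46 each, and that at 46 Mb in 19q13.2 had 43. Outside chromosome 19, windows in 22q12.1 (from 25 Mb) and 22q13.32 (from 47 Mb) had 43 peaks each. The mean over 2844 windows was 8.27 ± 6.34 (SD), and 22 windows had no peak. The variance-to-mean ratio of 4.86 compared with 2.11 on average and 2.20 at most in 1000 random placements (permutation p = 0.002, the smallest these can give). The median distance between neighbouring peaks was 62560 bp, against 78592 bp at random (permutation p = 0.002).

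The longest stretches of sequence without a peak were 2.22 Mb in 5q13.2 (68779139 to 70998651), 2.02 Mb in 15q21.3 (51574147 to 53597464) and 1.73 Mb in 1p31.1 (83306637 to 85037062). In 1000 random placements the longest stretch had a median of 1.43 Mb. It was at least as long as that in 5q13.2 in 2 placements, as that in 15q21.3 in 16 and as that in 1p31.1 in 113. The placements ignored mappability, so these stretches may hold sequence to which reads do not map.

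Density differed several-fold between chromosomes. Chromosome 19 stood highest, at 25.6 peaks per Mb (95% interval 19.99 to 31.07, bands resampled), followed by chromosome 20 at 14.07 (11.7 to 16.96) and chromosome 22 at 14.06 (9.82 to 18.6). Chromosome 16 was close to these at 14.02. The lowest were chromosome 13 at 6.15 (5.23 to 7.36), chromosome 4 at 6.279 (5.37 to 7.46) and chromosome 3 at 6.281 (5.69 to 6.95). The background at the summit also differed between chromosome arms. Its median was at least 1.45 times that of the median arm in 7 of 41 arms, and at most 1.17 times in the rest. The 7 were both arms of chromosomes 8, 16 and 20 and the long arm of chromosome 19. It was 1.42 fragments on 20q and 1.57 on 19q, against 0.944 on the median arm, and 0.786 on 9p, the lowest. An arm median can hide raised parts. On 5q, at 1.17 times the median arm, the background was 1.42 in 5q23.2, 1.49 in 5q23.3 and 1.42 in 5q35.3, but 0.676 in 5q21.3. Leaving out the 7 arms therefore does not leave out every region of raised background.

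**Figure D1:**
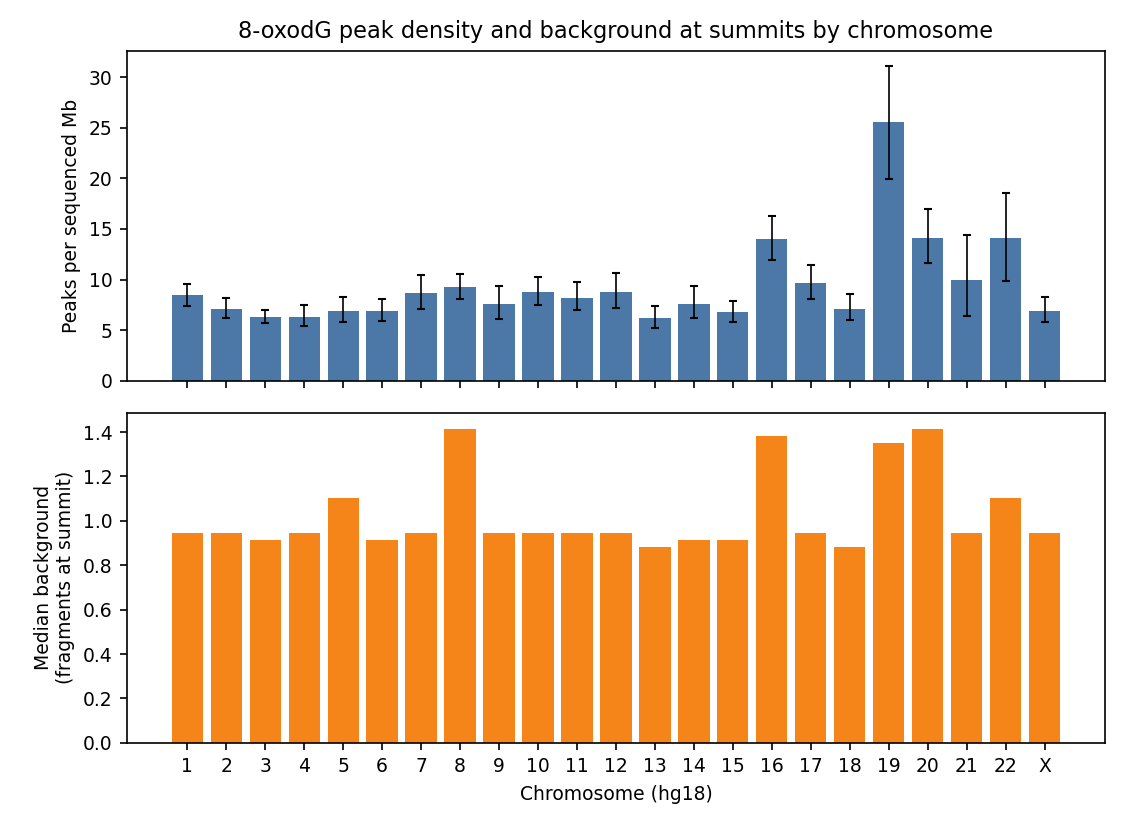
Upper bars show peaks per sequenced Mb for each chromosome, with 95% intervals from resampled bands as error bars, and lower bars the median background at peak summits in fragments. Chromosome 19 is highest in density at 25.6 peaks per Mb, and the background is raised on chromosomes 8, 16, 19 and 20.

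Across the 22 autosomes, density rose with genes per Mb, with genes of all types counted. Pearson's r was 0.839 (permutation p = 9e-05) and Spearman's rho 0.693 (permutation p = 0.0005, adjusted over 2 relations 0.001). Without chromosomes 19 and 22, the autosomes farthest from the median gene density, r was 0.547 (permutation p = 0.0146) and rho 0.6. Density fell with chromosome length, with r = −0.519 (permutation p = 0.00947) and rho = −0.591 (permutation p = 0.00462, adjusted 0.00462), and without chromosomes 1 and 2 r was −0.575. Without the 4 chromosomes that have an arm of raised background, an omission chosen after seeing the data, the relation with length no longer passed the threshold (rho = −0.428, permutation p = 0.0788).

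Bands that stain lightly with Giemsa, which are richer in genes and replicate earlier than dark bands, held more peaks. Giemsa-negative bands averaged 9.36 ± 6.04 peaks per Mb (SD over 409 bands), and the darkest classes, gpos75 and gpos100, 5.89 ± 2.10 (170 bands). The ratio was 1.59 (95% interval 1.46 to 1.73, permutation p = 1e-05, the smallest that 100000 permutations can give). Giemsa-negative bands were higher on 21 of 23 chromosomes. The rest, chromosomes 19 and 22, have no band of the darkest classes and could not be compared. Both enter the ratio only through their Giemsa-negative bands. With chromosome 19 left out the ratio was 1.53. The order of the classes was not a steady decline from light to dark. Bands of class gpos25 averaged 10.6 and those of gpos50 9.15, close to the Giemsa-negative bands, and the drop came at gpos75 (6.49) and gpos100 (5.22). The background at summits fell at the same step, with a median over bands of 0.944 (gneg), 0.951 (gpos25) and 0.944 (gpos50) against 0.849 (gpos75) and 0.786 (gpos100). Fold enrichment did not follow this pattern. The median fold enrichment per band averaged 11.8 in Giemsa-negative and 11.7 in the darkest bands (ratio 1.01, 95% interval 0.983 to 1.04, permutation p = 0.647).

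**Figure D2:**
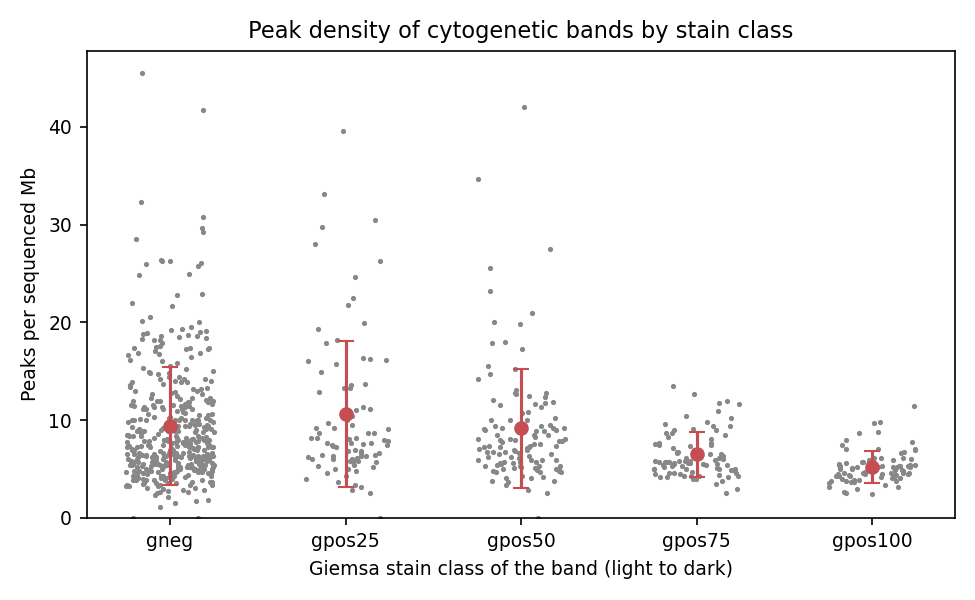
Each grey point is a cytogenetic band, placed by its Giemsa class from light to dark, with its peaks per sequenced Mb on the vertical axis, and red symbols give the mean and SD over bands. The means are 9.36, 10.6, 9.15, 6.49 and 5.22 from gneg to gpos100.

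Among stained bands with at least 1 Mb of sequence, 19q13.33 had the highest density, with 173 peaks in 3.8 Mb, or 45.5 per Mb (95% interval 39.0 to 52.8). It was followed by 22q13.32 (42.0), 19q13.42 (41.7), 19q13.2 (39.5), Xp22.32 (34.7), 19q13.32 (33.2), 7p22.3 (32.4), 19p13.13 (30.8), 19p13.12 (30.4) and 16q24.2 (29.7). The long and the short arm of chromosome 19 thus supplied 6 of these 10 bands. The band 9p12 had 0 peaks in 1.95 Mb, which by counting error alone allows a density of up to 1.89 per Mb. Densities took no account of mappability, so bands with few or no peaks may hold sequence to which reads do not map. The next lowest were 3q25.31, with 2 peaks in 1.8 Mb (1.11 per Mb), 15q15.3 (1.54), 3q13.12 (1.76), Xq21.32 (1.88), 5p14.2 (2.14), 3q25.33 (2.31), 1p21.1 (2.45), 1q42.12 (2.5) and 5q22.2 (2.5), with 9p21.3 tied at 2.5. In most of these the counts were small, and the interval for 3q25.31 reached from 0.135 to 4.01.

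Chromosome ends held more peaks than the rest. The outermost stained band of each arm averaged 16.5 ± 7.10 peaks per Mb (SD over 41 bands), and the other 743 bands 8.29 ± 5.44. The ratio was 1.99 (95% interval 1.72 to 2.27; permutation p = 1e-05, the smallest possible), with higher terminal bands on 20 of 23 chromosomes. The highest terminal bands were 7p22.3 (32.4), 19p13.3 (29.6) and 11p15.5 (29.3). Not every end was dense, as 9p24.3 (3.64), 3p26.3 (3.75) and 18p11.32 (4.14) lay below the mean of the inner bands. The background at summits was also higher in terminal bands, at 1.22 ± 0.340 fragments against 0.980 ± 0.245 (SD over 41 and 739 bands).

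Of the 10 fixed lists of bands, those with a density apart from random lists of the same stain classes numbered 2. Gene-rich terminal bands had a median of 17.9 peaks per Mb, 2.35 times that of random lists (adjusted permutation p = 0.012), and all 10 lay above the genome median. The highest were 19p13.3 (29.6) and 11p15.5 (29.3), and the lowest 1p36.33 (11.16) and 4p16.3 (11.5). Set against the other 31 terminal bands, whose median was 14.9, they did not differ detectably (permutation p = 0.357). Bands of the clusters of KRAB zinc finger genes, a large family of transcriptional repressors, had a median of 19.1, 2.42 times that of random lists (adjusted permutation p = 0.049), with 5 of 6 above the genome median. The highest were 19q13.41 (28.0) and 19p13.2 (21.8), and the lowest 19p12 (5.84) and 19q13.12 (13.333). All 6 lie on chromosome 19, where the other 11 bands had a median of 30.4 (permutation p = 0.094). The call for this list was lost in 8 of 9 alternatives, where the ratio was 1.81 to 2.56 and the adjusted permutation p lay between 0.055 and 0.271, and in the other it was 0.05, just under the threshold.

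The other 8 lists did not differ detectably from random lists after adjustment, though the list with a single band could not have passed. Bands of common fragile sites, where very long genes break under replication stress, had a median of 5.74 peaks per Mb, 1.00 times that of random lists (adjusted permutation p = 0.929), from 4.02 in Xp21.1 and 4.15 in 10q21.3 to 8.31 in 20p12.1 and 9.14 in 6q26. Of the 13, 2 lay above the genome median. The bands of the replication-dependent histone genes had a median of 6.54 (0.861 times, adjusted permutation p = 0.801), with 3.75 in 1q21.2, 6.54 in 6p22.2 and 8.95 in 6p22.1. The HOX clusters, which set body-axis identity, had a median of 6.23 (0.788 times, adjusted permutation p = 0.540), with 4.19 in 7p15.2, 4.88 in 2q31.1, 7.59 in 17q21.32 and 10.2 in 12q13.13. Olfactory receptor clusters had a median of 7.71 (1.11 times, adjusted permutation p = 0.819), from 3.59 in 11q11 and 7.59 in 11p15.4 to 9.39 in 11q12.1 and 11.6 in 14q11.2.

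Lists tied to the breast epithelial line did not pass the test either. The keratin clusters and the epidermal differentiation complex, which encode structural proteins of epithelia, had 10.2 peaks per Mb in 12q13.13, 12.7 in 1q21.3 and 16.4 in 17q21.2, a median 1.66 times that of random lists (adjusted permutation p = 0.420). All 5 bands of breast oncogenes lay above the genome median (1.414 times random lists, adjusted permutation p = 0.413). Of these, 8q24.21, 8p11.23 and 20q13.2 lie on arms of raised background, with 1.57, 1.68 and 1.42 fragments at summits, and 11q13.3 and 17q12 do not. With peaks scaled by arm background the ratio was 1.33, and without the raised arms 2.34 (adjusted permutation p = 0.457 and 0.263). The density was 26.3 in 11q13.3, 11.7 in 8q24.21, the band of MYC, 9.22 in 17q12, the band of the receptor gene ERBB2, and 8.00 in 8p11.23. The lists were set by band name, and the positions of their genes on hg18 were not checked. Bands described as gained in MCF10A had 11.7 in 8q24.21, 11.9 in 1q32.1, 12.4 in 5q35.3 and 33.2 in 19q13.32 (1.55 times random lists, adjusted permutation p = 0.413). The median background at summits in these bands was 1.57, 0.944, 1.42 and 1.57 fragments, in the same order. The single band described as lost, 9p21.3 with the tumour suppressor CDKN2A, had 14 peaks in 5.6 Mb, or 2.5 per Mb (95% interval 1.37 to 4.19), 0.5 times that of random bands of its class. Its permutation p of 0.0494 became 0.165 after adjustment. With 1 band drawn from the 81 of its class, even the lowest rank would not have passed after adjustment beside the other lists. The test could therefore not call 9p21.3, and the lowest adjusted permutation p in its alternatives was 0.0833. The median background at summits in 9p21.3 was 0.535 fragments, against 0.786 on 9p and 0.460 at the lowest in the list. Fewer copies in the library and less 8-oxodG cannot be told apart here.

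**Figure D3:**
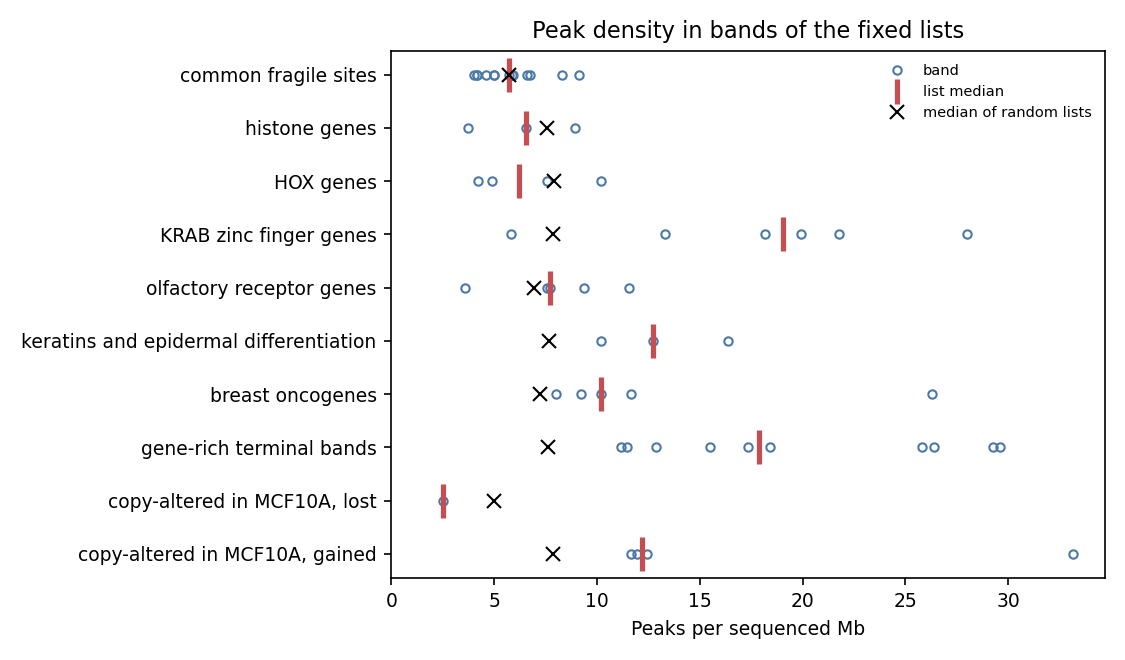
Circles show the peaks per sequenced Mb of each band in the 10 fixed lists, red bars the list median and crosses the median of 10000 random lists with the same stain classes. The medians of the zinc finger and gene-rich terminal lists, 19.1 and 17.9, lie farthest to the right of their crosses.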

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

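Tests on arms of raised background and on scaled peaks were chosen after the results were seen. The higher density of Giemsa-negative bands and of terminal bands kept its direction and passed its threshold in all 12 alternatives each, with ratios from 1.17 to 2.03 and from 1.83 to 2.63; with peaks scaled by band background they were 1.46 and 1.83. Clustering beyond random placement passed in all 8, and the rise of chromosome density with genes per Mb in all 8 (rho from 0.597 to 0.770). The fall of density with length passed in 6 of 7, and without the 4 chromosomes with an arm of raised background rho was −0.428 (p = 0.0788), with fewer chromosomes tested. The number of peaks was by construction 11841 among peaks of at least median width and 11821 among those of at least median fold enrichment.

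The number of lists called fell from 2 to 1 in 9 alternatives, which were joined peaks, peaks of at least median fold enrichment, scaled peaks, covered bases, autosomes only, bands of at least 1 Mb, the list mean, the omission of raised arms and single chromosomes left out, of which 9 of 23 had this effect (1, 2, 3, 8, 11, 12, 15, 19 and X); the cause was not tested. With 8 of these 9 left out the adjusted p of the zinc finger list was 0.052 to 0.067, and without chromosome 19 it has no band. The gene-rich terminal list was called in all of these alternatives, with adjusted p from 0.002 to 0.01, and at most 0.03 with any chromosome left out. The zinc finger list was therefore the one lost. Lists that were never called crossed 1 in either direction. The ratio for fragile sites was 0.768 with peaks of at least median width, 0.785 with those of at least median fold enrichment, 0.992 with scaled peaks, 0.958 with covered bases, 0.994 on autosomes, 0.888 as a mean and 0.9 without raised arms. For histone bands it was 1.13 with peaks of at least median width, and for olfactory receptor bands 0.960 as a mean. Without chromosome 6, which leaves only 1q21.2 in the histone list, the histone ratio was 0.494 (adjusted permutation p = 0.276). The causes were not tested.

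Leaving out a replicate was not run because the list pools the samples. Density against GC content and band gene density, partial correlations, draws matched on gene density and the gene tests were not run, since no sequence or gene annotation of hg18 was used here. The read depth is unknown, so what it limits could not be said; the lowest pileup in the list was 10.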

Other observations

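Tests on chromosomes 8, 16 and 20 taken singly, on copy gain of chromosome 19, on both references of arms and on local background were chosen only after the result was seen, as were the distance classes and the single regions named next.

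Peak density by distance from the chromosome end formed a broad zone rather than a step. It was 14.7 peaks per Mb in the outermost 1 Mb, 17.8 from 1 to 2 Mb (95% interval 14.4 to 21.4), 17.02 from 2 to 5 Mb, 12.9 from 5 to 10 Mb, 9.44 from 10 to 20 Mb, 7.34 from 20 to 50 Mb and 6.14 (5.53 to 6.81) beyond 50 Mb. The last class holds only the 16 chromosomes long enough to reach it. On those 16 alone the density was 14.3 in the outermost 1 Mb, 16.964 from 1 to 2 Mb, 15.974 from 2 to 5 Mb, 8.31 from 10 to 20 Mb and 6.76 from 20 to 50 Mb. Without chromosome 19 the class from 2 to 5 Mb had 16.2. In 9p21.3, the band of CDKN2A, the 14 peaks left stretches of 1.48 Mb (22664749 to 24148591) and 0.8002 Mb (21629665 to 22429883) without a peak. The median background in this band was 0.535, near the lowest in the list (0.460), so a lower copy number was not told apart from less 8-oxodG.

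In 14q32.32, 14 peaks lay within 51.4 kb (102406071 to 102457426), with folds from 11.3 to 275 and pileups from 16 to 400. Their median background was 0.469, and 9 of them were within 0.02 of the lowest background in the list. Whether these peaks came from genomic DNA or from other DNA in the library, such as a cDNA or a plasmid, was not tested, so the folds here cannot be read as 8-oxodG at this place. The 28 peaks of at least 5 kb had a median background of 5.46, which is 5.42 times that of all peaks. The background at summits took steps of 0.0157 fragments, with 93.2% of peaks within 0.0005 of a whole multiple, against 6.36% by chance.

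Peak density on chromosomes 8, 16 and 20 went with a raised background on their arms, and a candidate explanation is that extra copies of these arms in the library eased detection. Pileup and background were divided by each arm's ratio and the same thresholds applied, which kept 22724 peaks. Copy number was to be excluded as the whole cause only where the lower bound of the scaled ratio in stained bands stayed above 1.1. For the 3 together the ratio went from 1.45 to 1.22 (95% interval 1.08 to 1.37) against all other autosomal arms and from 1.53 to 1.27 (1.12 to 1.43) against arms without raised background and outside chromosome 19, both above 1 but on either side of that limit, so copy number stays open. Chromosome 16 went from 1.71 to 1.502 (1.255 to 1.81) and chromosome 20 from 1.71 to 1.47 (1.17 to 1.84) against all other arms, and to 1.58 (1.32 to 1.88) and 1.55 (1.24 to 1.95) against the narrower reference, which argues against copy number as their whole cause, with GC content open and no biological explanation tested. Chromosome 8 had no excess beyond its interval against all other arms (1.11, 0.964 to 1.28; 0.915 after scaling) and a small one against the narrower reference (1.22, 1.06 to 1.40; 0.981 after scaling), so the test decides nothing there.

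For chromosome 19, extra copies were taken to raise the density only where the background is raised, a premise that was not tested. The short arm, with a background 1.07 times that of the median arm, had 3.09 times the density of all other autosomal arms in stained bands (2.54 to 3.65, 5 bands). The long arm, after scaling, still had 3.03 times (2.16 to 3.83, 10 bands). These intervals resample few neighbouring bands as if independent, so they may be too narrow. A larger share of lightly stained bands was also argued against, since the density was 3.02 times that expected from stain classes (2.46 to 3.58). GC content and gene density, which were not tested by band, stay open, and no biological explanation was tested.

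The higher density toward chromosome ends may reflect that 38 of 41 terminal bands are Giemsa-negative, that arms of raised background carry it, or that the local background eases detection, since it averaged 1.22 in terminal and 0.980 in other bands (ratio 1.248, permutation p = 1e-05, the smallest possible). Among Giemsa-negative bands alone the terminal to other density ratio was 1.95, and without the arms of raised background it was 2.10 (permutation p = 1e-05 each). Bringing each band's pileup and background down to a shared background of 0.786 kept 20154 peaks, and the ratio was 1.83 (permutation p = 1e-05). These values argue against each of the 3 as the whole cause. GC content and gene density by band stay open, and no biological explanation was tested.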
